A study of Mus musculus with 16 samples.

How the data were processed

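RNA was measured in 16 libraries of tumours grown from MC38 cells, a mouse colon carcinoma line, grafted under the skin of mice. Per the labels, total RNA was extracted with Trizol. The labels put 4 libraries into each of 4 groups, namely control, exercise, anti-PD-L1 and exercise with anti-PD-L1, which is called the combination here. The series title speaks of PD-1 blockade while the labels name anti-PD-L1, and the name in the labels is used. Nothing in the labels says whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

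The values deposited by the authors are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with 2 decimals, for 18480 entries per library. HISAT, Bowtie2 and the build GRCm38.p6 are named in the submitters' processing notes, with no version or role. The library kit and the program that computed the FPKM values are not given in the sources used here. Of the entries, 17960 carried a symbol of the RefSeq annotation of GRCm38.p6, from which all coordinates were taken, and 18259 carried a symbol or a synonym. Symbols that read as dates stood on 26 entries and were kept as they were. A further 3 symbols stood on 2 entries each, and 9 entries were at 0 in every library.

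FPKM hold no read counts. Among 106 genes with low values, 63.9% of 1033 values lay within 0.15 of a whole multiple of the smallest value of their gene, and in 50 of these genes a large majority did. The smallest value of each gene counts among these by definition, and some others do by chance. Whole reads were therefore not recovered for most genes, the depth of the libraries is unknown, and no counting interval is given. FPKM summed to between 478672 and 529732 per library, and between 11293 and 11873 genes reached 1 FPKM.

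Values were taken as log2(FPKM + 1), so fold changes are on that scale, which understates the change of genes with low values. Genes with at least 1 FPKM in at least 4 libraries were tested, 11868 in all. One limma model (limma 3.58.1 in R 4.3.3, empirical Bayes with trend and robust settings) was fitted to the 16 libraries with the group as its only term. The pairwise comparisons and the interaction of exercise and antibody were contrasts of that model. P-values were adjusted by the Benjamini-Hochberg method within each contrast at a threshold of 0.05. The design had been written for counts or for normalized values, and the form for normalized values was used.

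The gene lists, the design, the rule for named genes and all alternatives except those said to be added were fixed before the data were examined. Of 35 gene lists, 28 had at least 5 tested members and were tested with camera at a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry. Fry tests whether the genes of a list move on balance in one direction and does not compare them with other genes. The mean log2(FPKM + 1) of each list was also compared between groups by a two-sided exact permutation test, for which 0.0286 is the smallest p that 4 libraries against 4 can give. Named genes were up to 10 with the largest rise and 10 with the largest fall among those past the threshold whose groups did not overlap, or otherwise the 5 with the smallest p. A fixed panel of genes and up to 4 members with the smallest p of each list described were named as well. Other genes that are named were chosen after their values were seen, which is said where they appear. Some genes are not reported here.

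The model was tested on simulated data with the means and residual spread of the 11868 genes, in which 200 genes were changed. For anti-PD-L1 against control, 89% of the genes changed by 1 on the log2 scale and 100% of those changed by 2 were recovered, with 2.05% false calls. For exercise against control the recovered shares were 92% and 99%, with 2.53% false calls. For the combination they were 92% and 100% against control, 85% and 99% against anti-PD-L1, and 90% and 100% against exercise. False calls there were 6.8%, 5.61% and 4.95%, so the first and second lay above the threshold of 5%. For the interaction 76% and 97% were recovered, with 2.79% false calls. The simulated genes varied independently of each other, which real genes do not. No libraries held identical values, and correlations across genes ranged from 0.957 to 0.989 within groups and from 0.933 to 0.990 between groups. The highest correlation was thus between libraries of different groups.

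The alternatives were limma without trend and robust settings, quantile normalization, centring of the libraries on their medians, no filter on low values, a mean of at least 5 FPKM, pseudocounts of 0.1 and 0.01, only the groups compared, the replicate number as a block, library weights, a fold threshold, and leaving out each library in turn. Leaving out controls 1 and 2 together was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Tests made for counts were not used, since the values are not counts.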

Results

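Expression was measured in 16 libraries from MC38 tumours, with 4 libraries in each of the control, exercise, anti-PD-L1 and combination groups. FPKM sums lay between 478672 and 529732 per library, and the 10 highest genes held between 6.82% and 8.73% of the sum. On the first principal component, which held 30.1% of the variance, controls 1 and 2 lay at -30.8 and -41.4, farther from 0 than the other libraries. Several genes that mark immune cells were below the level needed for testing. Cd8a, a marker of cytotoxic T cells, measured 0.413 ± 0.29 FPKM (SD, n = 4) in control and 1.02 ± 0.81 in anti-PD-L1 tumours. Ifng, which encodes interferon gamma, measured 0.0525 ± 0.055 and 0.498 ± 0.526 FPKM in the same groups. Pdcd1, Foxp3, Ncr1, Adipoq and Krt8 were also not tested.

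The first comparison asked how the tumours differed with antibody alone. Genes of antigen presentation on MHC class I were higher in anti-PD-L1 than in control tumours. Psmb9, a subunit of the immunoproteasome (chromosome 17, 34182030 to 34187330 in the RefSeq annotation of GRCm38.p6), rose from 18.7 ± 5.5 to 63.1 ± 14.98 FPKM (SD, n = 4 each), a log2 fold change of 1.72 with a standard error of 0.21. Tap1, a part of the transporter that carries peptides into the endoplasmic reticulum (chromosome 17, 34187556 to 34197225), rose from 23.6 ± 6.21 to 66.9 ± 14.3 FPKM. H2-T22, a non-classical class I gene (chromosome 17, 36037128 to 36042742), rose from 43.3 ± 8.47 to 113 ± 15.1 FPKM. In all 3 genes each anti-PD-L1 library lay above each control library. H2-T22, H2-T10 and other class I heavy chain genes have near-identical copies that can share reads, and their values are uncertain for that reason. The RefSeq annotation marks H2-T10 as a transcribed pseudogene.

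**Figure D1:**
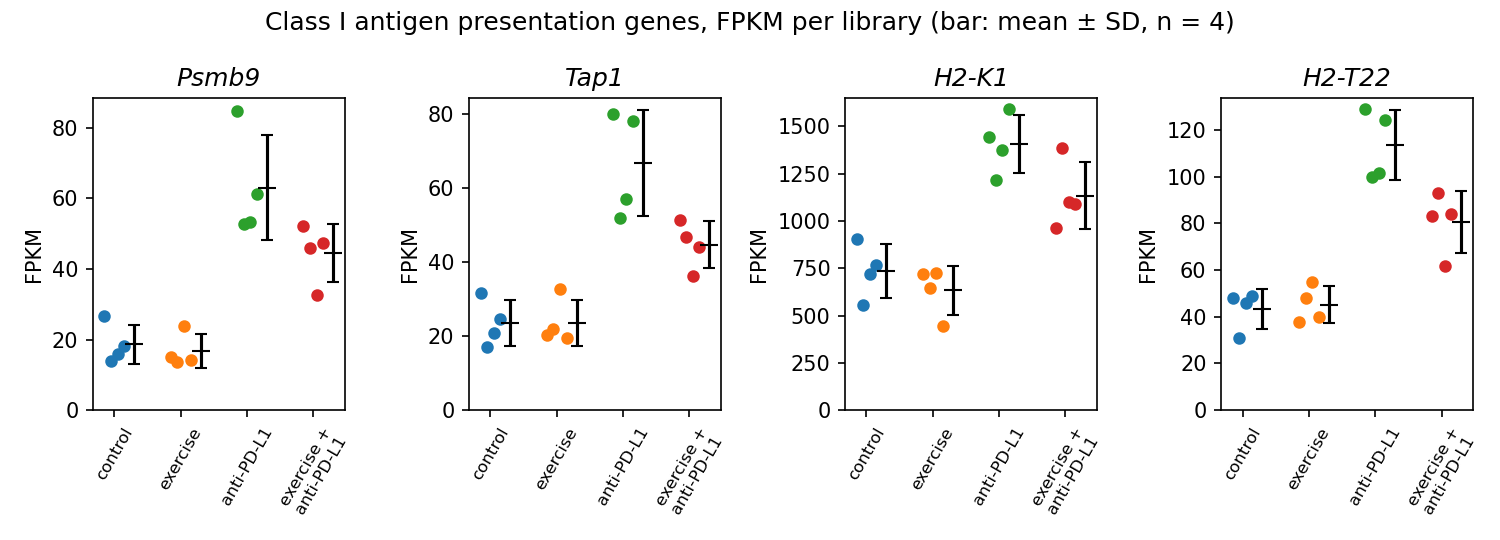
FPKM of Psmb9, Tap1, H2-K1 and H2-T22 per library (y axis) in the 4 groups (x axis), with 1 point per library and bars for the mean and SD of 4 libraries. The anti-PD-L1 libraries of Psmb9 lay between 52.8 and 84.8 FPKM, above the highest control library at 26.6 FPKM.

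Of 11868 genes, 30 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 19 higher and 11 lower, and 15 of them changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 in limma there were 2789 genes, 922 higher and 1867 lower. The libraries of both groups did not overlap for 10.8% of genes, where chance gives 2.86%. The adjusted p in limma was 0.002 for Psmb9, 0.00368 for Tap1 and 0.00166 for H2-T22. Other genes that rose were Gbp9, an interferon-induced GTPase, by 2.03 ± 0.37 (log2 fold change ± standard error), Il1rn, the antagonist of the interleukin 1 receptor, by 1.69 ± 0.31, Nkg7, a gene of cytotoxic lymphocytes, by 1.26 ± 0.25, and Psmb8, another immunoproteasome subunit, by 1.18 ± 0.20. Apol6, H2-T10 and Sp140 also rose, with log2 fold changes between 1.26 and 1.43.

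Genes that fell included 2 enzymes of sterol synthesis. Idi1, the isopentenyl diphosphate isomerase (chromosome 13, 8885606 to 8892396), fell from 8.08 ± 2.58 to 2.08 ± 0.985 FPKM, and Cyp51, the lanosterol demethylase (chromosome 5, 4080674 to 4104697), from 39.2 ± 6.47 to 17.5 ± 4.78 FPKM. Their adjusted p in limma was 0.0338 and 0.0436, and for both genes each anti-PD-L1 library lay below each control library. Ctxn1 fell from 41.6 ± 2.84 to 20.6 ± 2.90 FPKM, and Kcne3, a potassium channel subunit, from 4.97 ± 1.51 to 1.498 ± 0.645 FPKM. Hmgb3, Arhgap19, Dennd2a, Pros1, Mrps6 and Ammecr1 fell as well, with log2 fold changes between -0.95 and -0.50.

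The number of genes that passed depended on single libraries. It was 10, 6, 17 and 767 without control 1, 2, 3 and 4, and 11, 6, 55 and 7 without anti-PD-L1 library 1, 2, 3 and 4. Without controls 1 and 2 together, a fit added after seeing the data, it was 4. Psmb9, Tap1 and H2-T22 passed in each of the 27 alternative fits run for them, and Ctxn1 in 26 of 27. The 27 include fits without an exercise or combination library, which keep the fold change of this comparison and alter its p-value through the shared spread. Idi1 passed in 18, Psmb8 in 20, Gbp9 in 15, and Cyp51 and Il1rn in 14 of the 27. Of 26 fits each, Kcne3 and Apol6 passed in 14 and Nkg7 in 11, the fewest of the named genes, with a highest adjusted p of 0.309 for Nkg7 in limma.

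Among the gene lists, camera called 16 of 28, 12 higher and 4 lower, and fry called 3. None kept its call with an estimated correlation. Of the 16 tested members of the MHC class I presentation list, 8 rose over all genes and 13 rose when adjusted over the list alone, with a median log2 fold change of 0.89. The camera adjusted p was 3.4e-18, and the adjusted p = 0.101 with an estimated correlation. Of 20 members of the interferon gamma response, 2 rose over all genes, Psmb9 and Tap1, and 18 adjusted over the list alone, with a median of 1.68. Its camera adjusted p was 5.94e-21, and the adjusted p = 0.219 with an estimated correlation. Gbp2, an interferon-induced GTPase, had a log2 fold change of 2.21 ± 0.44. Of 19 members of the type I interferon response, 0 passed over all genes in limma, where 5 rose adjusted over the list alone, with a median of 1.23. Its camera adjusted p was 1.74e-09, and the adjusted p = 0.366 with an estimated correlation. Without anti-PD-L1 library 1 its median was 0.74.

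Of 7 tested genes of cytotoxic lymphocytes, 1 rose over all genes, Nkg7, and 5 adjusted over the list alone, with a median of 0.81. Nkg7 passed in 11 of 26 alternative fits. With camera the adjusted p was 0.000407, and the adjusted p = 0.317 with an estimated correlation. Gzmb, which encodes granzyme B, measured 2.53 ± 1.23 FPKM in control and 11.8 ± 5.28 in anti-PD-L1 tumours, with an adjusted p of 0.0588 in limma. Prf1, which encodes perforin, measured 1.58 ± 1.11 and 9.15 ± 5.33 FPKM, with an adjusted p of 0.0714 in limma. Cd274, which encodes PD-L1, measured 4.74 ± 1.01 and 11.8 ± 3.65 FPKM, with an adjusted p of 0.0762 in limma.

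Cell cycle genes had a median of -0.55, with all 25 members below 0. By limma, 0 members passed over all genes and 22 fell adjusted over the list alone, among them Bub1b, a spindle checkpoint kinase, at -0.61 ± 0.12, and Plk1, a mitotic kinase, at -0.74 ± 0.18. Camera gave an adjusted p of 4.1e-11, and the adjusted p = 0.366 with an estimated correlation. Mki67, a marker of proliferation, measured 54.2 ± 9.22 FPKM in control and 30.2 ± 3.56 in anti-PD-L1 tumours, with an adjusted p of 0.129 in limma. Hypoxia genes had a median of 0.64 over 16 members, of which 0 passed over all genes in limma and 4 adjusted over the list alone, and an adjusted p = 0.366 with an estimated correlation. Car9, carbonic anhydrase 9, had a log2 fold change of 1.33 ± 0.46.

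Markers of other cell types were also tested for the antibody alone. Monocyte and macrophage genes had a median of -1.15 over 15 members, with 4 lower adjusted over the list alone and 0 over all genes in limma. Endothelial and pericyte genes had a median of -0.63 over 15 members, with 0 passing on either count in limma. Camera called both lower, with an adjusted p = 0.386 with an estimated correlation for each. Adgre1, a macrophage marker, measured 10.8 ± 6.93 FPKM in control and 3.42 ± 0.713 in anti-PD-L1 tumours. Without controls 1 and 2 both calls were lost, with medians of -0.33 and -0.08, and without control 2 alone the endothelial median was -0.35. The other lists that camera called were higher for glycolysis, immediate early and heat shock, chemokine, classically activated macrophage, glucocorticoid target, circadian clock and MHC class II genes, and lower for oxidative phosphorylation. With an estimated correlation none of these was called, with an adjusted p = 0.476 for MHC class II, 0.376 for oxidative phosphorylation and 0.366 for each of the others. Over all genes 0 members of these lists passed in limma. The chemokine call was lost without control 3 or 4, at medians of 0.35 and 0.56, the clock call without anti-PD-L1 library 4, at 0.06, and the glucocorticoid call without anti-PD-L1 library 3 or 4, at 0.33 and 0.17. The MHC class II call was lost without control 3 or 4 or anti-PD-L1 library 1 or 4, at 0.21, 0.30, 0.28 and 0.35. The classically activated macrophage call was lost without control 3 or 4, at 0.78 and 0.86, combination library 1, at 0.77, or anti-PD-L1 library 1, 2 or 4, at 0.78, 0.31 and 1.01. The oxidative phosphorylation call was lost without controls 1 and 2, at -0.05.

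**Figure D2:**
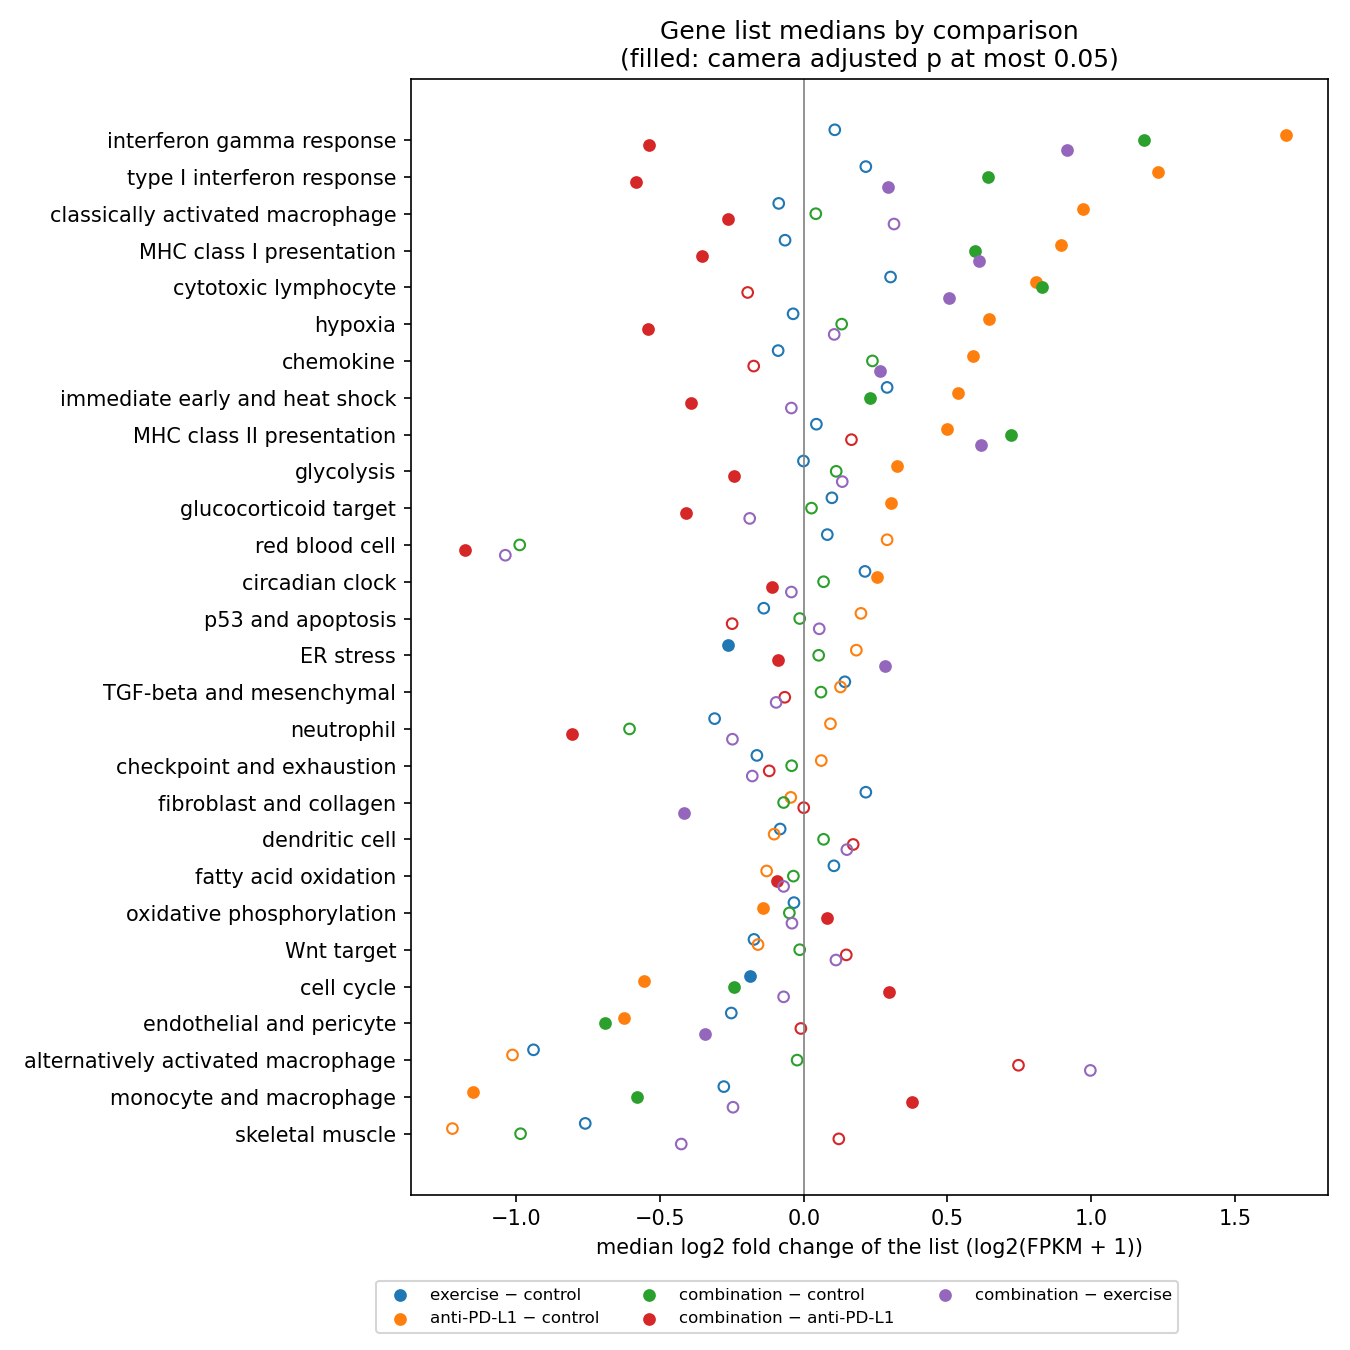
Median log2 fold change of the members of each gene list (x axis) for the 28 lists (y axis) in 5 comparisons, with filled points where camera at the preset correlation gave an adjusted p of at most 0.05. The interferon gamma response lay at 1.68 for anti-PD-L1 against control, and none of the calls held with an estimated correlation.

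The next comparison asked how exercise alone changed the tumours. The genes with the smallest p were Tra2a, a splicing regulator, at -0.64 ± 0.12, Dyrk1b, a kinase, at 0.64 ± 0.13, Itga10, an integrin, at 1.03 ± 0.21, and Xpo1, the nuclear export receptor, at -0.58 ± 0.12, each with an adjusted p of 0.181 in limma. The entry named 217615 had a log2 fold change of -0.42 ± 0.09. Krt14, a basal keratin, measured 20.4 ± 10.6 FPKM in control and 55.5 ± 15.7 in exercise tumours, with an adjusted p of 0.181 in limma. None of these passed the threshold. With limma, 0 genes passed and 2131 had an unadjusted p under 0.05, while the libraries of both groups did not overlap for 7.72% of genes, where chance gives 2.86%.

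Endoplasmic reticulum stress genes had a median of -0.26, with 12 of 12 members below 0. Over all genes 0 members passed in limma, and 3 fell when adjusted over the list alone, among them Trib3, a pseudokinase induced by this stress, at -0.94 ± 0.22. The camera adjusted p was 0.0099, and the adjusted p = 0.976 with an estimated correlation. The call was lost without control 2, at a median of -0.23. Cell cycle genes had a median of -0.19, with 24 of 25 below 0, and 0 members passed on either count in limma. With camera the adjusted p was 0.03, and the adjusted p = 0.976 with an estimated correlation. That call was lost without control 1, control 2, exercise 3 and exercise 4, at medians of -0.13, -0.17, -0.13 and -0.15, and without controls 1 and 2 together, at -0.03. The median was -0.30 without control 4 and -0.34 without exercise 1. Fry called 0 lists.

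The count of genes depended on exercise library 1. Without it, 611 genes passed in limma, 177 higher and 434 lower, and with library weights 2274 passed. With exercise 1 and control 4 in each other's place 928 passed, so the count of 0 holds for the labels as given. Genes named from the fit without exercise 1 were chosen after their values were seen. Mki67 fell by 1.28 ± 0.18, Smc4, a condensin subunit, by 1.24 ± 0.16, Kif11, a spindle motor, by 0.85 ± 0.11, and Lamc1, a laminin chain, rose by 0.83 ± 0.14. In that fit 4 cell cycle genes passed over all genes and 5 adjusted over the list alone, with a median of -0.34 and an adjusted p = 0.938 with an estimated correlation.

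**Figure D3:**
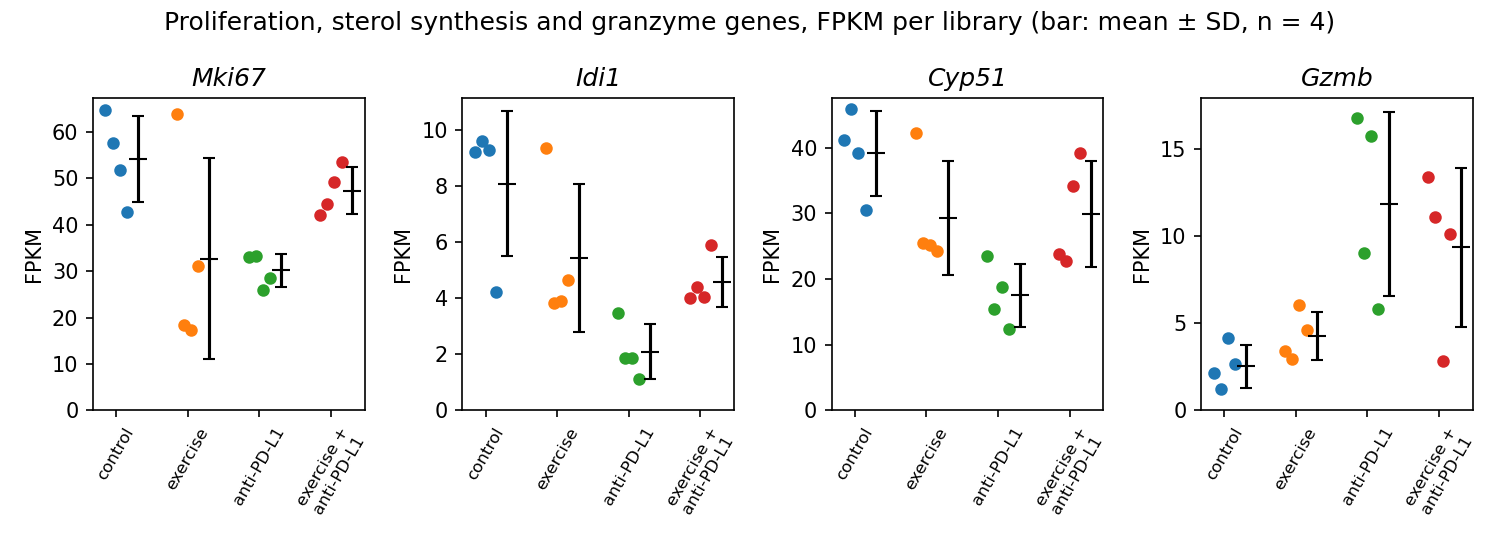
FPKM of Mki67, Idi1, Cyp51 and Gzmb per library (y axis) in the 4 groups (x axis), with 1 point per library and bars for the mean and SD of 4 libraries. Idi1 in exercise library 1 measured 9.36 FPKM, the highest of its group.

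The combination was compared with control next. Psmb9 measured 44.5 ± 8.30 FPKM in the combination, a log2 fold change of 1.23 ± 0.21, and H2-T22 measured 80.5 ± 13.2 FPKM, at 0.89 ± 0.16, each with an adjusted p of 0.245 in limma. H2-T10 was at 0.80 ± 0.15, Thbs2, a matrix thrombospondin, at -1.98 ± 0.37 and Ogfr at 0.40 ± 0.08. With limma, 0 genes passed, and 973 had an unadjusted p under 0.05. The libraries of both groups did not overlap for 3.83% of genes, where chance gives 2.86%. Interferon gamma response genes had a median of 1.18, with 20 of 20 members above 0. Over all genes 0 passed in limma and 14 rose adjusted over the list alone, with an adjusted p = 0.156 with an estimated correlation. MHC class I presentation genes had a median of 0.60, where 0 of 16 passed over all genes in limma and 10 rose adjusted over the list alone, with an adjusted p = 0.122 with an estimated correlation. Cytotoxic lymphocyte genes had a median of 0.83, where 0 of 7 passed over all genes in limma and 4 rose adjusted over the list alone, with an adjusted p = 0.156 with an estimated correlation. Gzmb measured 9.33 ± 4.54 FPKM. Endothelial and pericyte genes had a median of -0.69 with 15 of 15 members below 0, of which 0 passed on either count in limma, and an adjusted p = 0.485 with an estimated correlation. Without control 2 the median was -0.37, and without controls 1 and 2 that call was lost, at -0.10. Monocyte and macrophage genes had a median of -0.58, with 0 members past on either count in limma and an adjusted p = 0.732 with an estimated correlation. That call was lost without control 2 at -0.21 and combination library 2 at -0.23, and without controls 1 and 2 the median was 0.06. It was -0.89 without control 3. Camera called 9 lists in all and fry 0.

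Whether adding exercise to the antibody changed the tumours was tested by the combination against anti-PD-L1. Ctxn1 was at 0.48 ± 0.12, Insig1, a regulator of sterol synthesis, at 0.66 ± 0.17 and Mmp8, a neutrophil collagenase, at -1.07 ± 0.28, each with an adjusted p of 0.968 in limma. Zfp771 and Rnf145 were at 0.39 ± 0.10 and -0.30 ± 0.08. With limma, 0 genes passed and 468 had an unadjusted p under 0.05, while the libraries did not overlap for 2.24% of genes, where chance gives 2.86%. This comparison and anti-PD-L1 against control share the anti-PD-L1 libraries with opposite sign, so opposite changes in both arise together by chance. Cell cycle genes had a median of 0.30 with 25 of 25 members above 0, and 0 members passed on either count in limma. The exact permutation test of their mean gave p = 0.0571, with an adjusted p = 0.4. Camera gave an adjusted p of 3.04e-10, and the adjusted p = 0.307 with an estimated correlation. Mki67 measured 47.4 ± 5.11 FPKM in the combination. MHC class I presentation genes had a median of -0.35 with 16 of 16 below 0, and interferon gamma response genes a median of -0.54 with 19 of 20 below 0. The camera adjusted p was 3.63e-09 and 5.72e-09, and the adjusted p = 0.307 with an estimated correlation for both, with 0 members of either past on either count. The interferon median was -0.33 without anti-PD-L1 library 1. Hypoxia genes had a median of -0.54, with Car9 at -1.18 ± 0.46, and an adjusted p = 0.307 with an estimated correlation. Their median was -0.34 without combination library 4 and -0.345 without anti-PD-L1 library 4. Camera also called lists of other cell types, with medians of -0.81 for neutrophil, -1.18 for red blood cell, -0.26 for classically activated macrophage and 0.38 for monocyte and macrophage genes. The adjusted p = 0.307 with an estimated correlation for the first 3 of these and 0.561 for the last. Of their members 1 neutrophil gene passed adjusted over the list alone. The neutrophil call was lost without anti-PD-L1 library 2, at -0.28, and the red blood cell call without anti-PD-L1 library 4, at -0.08, while without library 2 its median was -1.94. The classically activated macrophage call was lost without combination library 1 or anti-PD-L1 library 1, 2 or 4, at medians between -0.36 and -0.07, and the median was -0.45 without combination library 4 and -0.56 without anti-PD-L1 library 3. The monocyte and macrophage call was lost without control 4, exercise 1, combination library 3 or 4 or anti-PD-L1 library 1, 2 or 3, at medians between 0.00 and 0.42, and the median was 0.62 without combination library 2. Camera called 16 lists and fry 0.

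The combination against exercise asked what the antibody added to exercise. Psmb9 was at 1.38 ± 0.21 and Ctxn1 at -0.79 ± 0.12, each with an adjusted p of 0.0561 in limma. H2-T10 was at 0.88 ± 0.15, Ulk3 at 0.54 ± 0.10 and Maml3, a Notch coactivator, at -0.58 ± 0.11. With limma, 0 genes passed and 1618 had an unadjusted p under 0.05, while the libraries did not overlap for 6.94% of genes, where chance gives 2.86%. Without exercise 1, 184 genes passed, without exercise 3 it was 1 and without combination library 3 it was 2. With exercise 1 and combination library 1 in each other's place 533 passed. MHC class I presentation genes had a median of 0.61, with 16 of 16 members above 0. By limma 0 passed over all genes and 10 rose adjusted over the list alone. With camera the adjusted p was 9.2e-14, and the adjusted p = 0.231 with an estimated correlation. Endoplasmic reticulum stress genes had a median of 0.28, where 0 of 12 passed over all genes in limma and 3 rose adjusted over the list alone, among them Trib3 at 1.19 ± 0.22, with an adjusted p = 0.233 with an estimated correlation. Fibroblast and collagen genes had a median of -0.42, with 0 members past on either count in limma and an adjusted p = 0.685 with an estimated correlation. That call was lost without combination library 2 at -0.21, and the median was -0.66 without combination library 4. Endothelial and pericyte genes had a median of -0.34, with 2 lower adjusted over the list alone and 0 over all genes in limma, and an adjusted p = 0.685 with an estimated correlation. Camera called 9 lists and fry 1, the MHC class I presentation list.

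The interaction tested whether the antibody effect differed with exercise. Cpt1a, which carries fatty acids into mitochondria, was at -1.12 ± 0.25, Bpgm at 0.74 ± 0.15, Letm2 at -0.72 ± 0.15, Lacc1 at 0.65 ± 0.15 and Defb25 at -0.80 ± 0.19, each with an adjusted p of 0.364 in limma. With limma, 0 genes passed and 1554 had an unadjusted p under 0.05. Without exercise 1 there were 224. Cell cycle genes had an interaction median of 0.47, with 25 of 25 above 0, 0 past over all genes in limma and 2 adjusted over the list alone, Mki67 at 1.53 ± 0.41 and Bub1, a checkpoint kinase, at 0.89 ± 0.26. Camera gave an adjusted p of 1.43e-07, and the adjusted p = 0.577 with an estimated correlation. Interferon gamma response genes had an interaction median of -0.74, with 0 members past on either count and an adjusted p = 0.577 with an estimated correlation. It was -0.43 without exercise 3, -0.46 without combination library 3 and -0.40 without anti-PD-L1 library 1. Fatty acid oxidation genes had a median of 0.01, a mean of -0.16 and a camera call for lower, with an adjusted p = 0.577 with an estimated correlation. That call was lost in 10 of the 16 fits without 1 library, in which the median lay between -0.11 and 0.03. Among the 4 members lower when adjusted over the list alone were Cpt1a, Acadl and Angptl4. Without exercise 3 camera called 5 lists and without combination library 4 it called 6, where all libraries gave 13.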

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

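The fit without controls 1 and 2 was added after seeing the data, and no other test in this part was chosen after its result was seen. A library was set apart where its gap to the nearest other library, divided by the range of its group of 4, was above the critical value of Dixon's test for 4 values. Chance sets apart about 1 in 20 groups, and 16 of 243 groups of values were set apart here, so single cases carry little weight.

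In anti-PD-L1 library 1, Cd8a measured 2.23 FPKM, Ifng 1.28, Cxcl9, a chemokine that attracts T cells, 49.94 and Apol6 7.19, each the highest of its group, and Ulk3 measured 10.94, the lowest. In anti-PD-L1 library 2, S100a8, a neutrophil gene, was highest at 9.58 FPKM. In exercise library 1, Idi1 was highest at 9.36 and Cyp51 at 42.22 FPKM, and in exercise library 3, Psmb9 at 23.82 and Mmp8 at 1.28 FPKM. In control 2, Acta1, skeletal muscle actin, was highest at 169.93 and Adipoq, an adipocyte gene, at 0.41 FPKM, and in control 4, Idi1 was lowest at 4.22 FPKM. In combination library 3, Tra2a was highest at 45.39 and Arg1, an arginase of macrophages, at 192.48 FPKM. In combination library 2, Maml3 was lowest at 3.8 FPKM.

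The effect of the antibody differed with exercise, by camera on the interaction at the preset correlation, for 13 lists, and for none with an estimated correlation. The interaction medians on the log2 scale were 0.653 for monocyte and macrophage genes, 1.218 for alternatively activated macrophage genes, 0.465 for cell cycle genes, 0.101 for oxidative phosphorylation and 0.01 for fatty acid oxidation. They were -0.737 for the interferon gamma response, -0.891 for the type I interferon response, -0.298 for MHC class I presentation, -0.406 for hypoxia, -0.187 for glycolysis, -0.713 for immediate early and heat shock genes, -0.508 for glucocorticoid targets and -0.293 for circadian clock genes. Of these lists, 2 members of the cell cycle list and 4 of the fatty acid oxidation list passed adjusted over the list alone, and 0 members of the others.

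Many of these calls rested on single libraries. Without exercise 3 or anti-PD-L1 library 1 the MHC class I median was -0.15 and -0.13, and the call was lost without exercise 3. The hypoxia call was lost without control 3, exercise 3, combination library 4 or anti-PD-L1 library 4, at -0.36, -0.20, -0.20 and -0.25. The glycolysis call was lost without control 4, exercise 2 or 3, combination library 4 or anti-PD-L1 library 3 or 4, at medians between -0.17 and -0.06. For monocyte and macrophage genes it was lost without control 1 or 2, exercise 1 or 3, combination library 4 or anti-PD-L1 library 2, at medians between 0.34 and 0.66, and without controls 1 and 2 together, at 0. For alternatively activated macrophage genes it was lost without control 2, at 0.62, combination library 4, at 1.08, and controls 1 and 2 together, at 0.37. Oxidative phosphorylation was not called without control 1 or 2, exercise 3 or 4, combination library 1 or 2 or anti-PD-L1 library 2, at medians between 0.08 and 0.11, nor without controls 1 and 2 together, at 0.02. The fatty acid oxidation call was lost without control 3 or 4, exercise 2, 3 or 4, combination library 1, 3 or 4 or anti-PD-L1 library 3 or 4, at medians between -0.11 and 0.03. Immediate early and heat shock genes were not called without exercise 3, combination library 4 or anti-PD-L1 library 4, at -0.55, -0.47 and -0.47. Circadian clock genes were not called without control 1 or 4, exercise 3, combination library 4 or anti-PD-L1 library 4, at medians between -0.31 and -0.11. The calls of the cell cycle, both interferon and glucocorticoid lists were kept in each of the 16 fits without 1 library. Their medians lay between 0.37 and 0.65 for cell cycle, -1.06 and -0.40 for interferon gamma, -1.25 and -0.47 for type I interferon and -0.69 and -0.33 for glucocorticoid genes.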

How the results depend on the processing

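Leaving out controls 1 and 2 together was chosen after seeing the data, and the other alternatives were planned. Of the gene values under the alternatives, 3067 kept their direction and side of the threshold, 161 lost a call and 68 gained one. A further 53 changed sign with no call in either fit, and a kept value may still have moved in size. Of the list values the numbers were 3344, 267, 105 and 142, by the direction of the list test. With all libraries 0 genes passed for exercise against control, and with library weights 2274, while leaving out 1 library gave 0 to 611, the highest without exercise 1. The 2 lists called there were 4 without a filter, 0 with an estimated correlation, 0 with fry, and 5 without controls 1 and 2, of which 4 were higher and 1 was among the 2, both lower. They were 0 to 7 without 1 library. For anti-PD-L1 against control the 30 genes became 117 with quantile normalization, 77 with centred libraries, 8 without a filter, 835 with library weights, 15 at a log2 fold change of at least 1, 4 without controls 1 and 2, and 6 to 767 without 1 library. The replicate block gave 15, of which 14 were among the 30, but same-number libraries correlated from -0.62 to 0.344, with 6 of 24 pairs over 0.1 and 5 of 24 closest to their own number. Between control and exercise 3 of 4 pairs were over 0.1, at 0.119, 0.197 and 0.291, and 1 at 0.005, and 3 were closest to their own number. In none of the pairs of groups were all 4 over 0.1, so the numbers were not taken to pair the samples, and the block left 0 genes and 2 lists for exercise. The 16 lists became 0 with an estimated correlation and 3 with fry. For the combination against control and against anti-PD-L1, 0 genes passed in each alternative, and the 9 and 16 lists became 0 with an estimated correlation and 0 with fry. For the combination against exercise, 2 genes passed with quantile normalization, 2 with centred libraries, 2 at a mean of at least 5 FPKM, 222 with library weights, 1 with only the groups compared and 0 to 184 without 1 library, and the 9 lists became 0 with an estimated correlation and 1 with fry. For the interaction, 0 to 224 genes passed without 1 library, and the 13 lists became 0 with an estimated correlation, 0 with fry and 5 to 14 without 1 library. Without controls 1 and 2 the median changed sign in 13 of 28 lists for exercise against control, 2 for anti-PD-L1 against control, 8 for the combination against control and 4 for the interaction, with a call in either fit for 1, 1, 2 and 4 of them. The direction of camera turned, with a call in either fit, for endothelial and pericyte genes for exercise against control (0.295) and the interaction (-0.297), monocyte and macrophage genes for the combination against control (0.059) and the interaction (0), alternatively activated macrophage genes for the combination against control (0.204) and MHC class II genes for the interaction (-0.394). An estimated correlation widens the spread of a list's test, no filter adds genes to the adjustment and the fold threshold removes genes, and for the other changes the cause was not tested. The depth of the libraries is unknown, so its effect on genes with low values could not be measured.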

Other observations

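The sterol gene lists were chosen after the main results were seen, as were the tests on near-identical copies and on dilution of the tumour cells, the interaction and the set tests of the sterol genes, their simulation, and the requirement that a bound be passed by more than 1 standard error. The other tests in this part were written before their results were seen.

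Further sterol genes beyond Idi1 and Cyp51 were examined. Of 15 such genes not seen first, 15 had a negative log2 fold change for anti-PD-L1 against control and 15 a positive one for the combination against anti-PD-L1. In limma 0 of them passed over all genes in either comparison, and 14 and 8 passed adjusted over the list alone. Camera on this list with an estimated correlation gave an unadjusted p of 0.0478 and 0.0192. Lss, the lanosterol synthase, was at -0.86 and 0.53, Mvd, a decarboxylase of the mevalonate pathway, at -0.85 and 0.73, and Msmo1, a sterol oxidase, at -1.04 and 0.66, examples chosen after their values were seen. Both comparisons use the same anti-PD-L1 libraries with opposite sign, so opposite signs arise together by chance. In 10000 simulations with no effect the first median was below 0 and the second above 0 in 33.8%, and all 15 genes followed that order in 0.9%. All 15 were below 0 in the first comparison in 6.11%. Neither these shares nor the camera p-values allow for the choice of the pathway after the results were seen. In the mean log2(FPKM + 1) of these genes, exercise library 1 measured 4.58, while the other exercise libraries lay between 3.91 and 3.95.

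For 7 lists with fewer than 5 tested members, scores over all members were compared by the two-sided exact permutation test. Keratinocyte and skin genes were 0.18 higher on the log2 scale with exercise than in control (exact p = 0.0286, adjusted p = 0.5 by Benjamini-Hochberg over the 35 lists). T cell genes were 0.16 and NK cell genes 0.12 higher in the combination than with exercise (exact p = 0.0286 and adjusted p = 0.2 for each). B and plasma cell genes were 0.07 lower with anti-PD-L1 than in control (exact p = 0.0286, adjusted p = 0.167). None of these passed the correction, for which at least 20 of the 35 lists would have had to reach the smallest p, so the design all but ruled out a pass. Differences from control with anti-PD-L1 were 0.06 for regulatory T cell, -0.01 for adipocyte and -0.07 for epithelial genes.

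The antibody effect without exercise and with it correlated across genes at 0.301 (permutation p = 0.22 over 4900 pairs of splits), where genes are not independent replicates. Of the 30 genes called for anti-PD-L1 against control, 29 had the same sign for the combination against exercise and 16 had an unadjusted p under 0.05 there, with a median log2 fold change of 0.37 in the called direction against 1.01. The genes were picked as extreme in the first comparison, so a smaller median in the second can come from the selection alone. Fold changes of exercise and of anti-PD-L1 against the same controls correlated at 0.493 with a covariance of 0.0494. Simulated groups with no effect gave a mean correlation of 0.474, between -0.14 and 0.871, and a mean covariance of 0.0181. Whether these simulated values hold for the measured controls in particular was not tested. With the controls split between the comparisons the correlation lay between -0.0491 and 0.426.

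The MHC class I presentation genes were higher with anti-PD-L1 than in control, with 8 of 16 members past over all genes in limma. Fry called the list and camera with an estimated correlation did not (adjusted p = 0.101). Without controls 1 and 2 the median was 0.881 with a standard error of 0.15, which argues against those libraries as the whole cause. Standard errors beside list medians in this part are those of the difference between groups in the list mean per library, not of the median. Members without near-identical copies had a median of 0.873 ± 0.197, so shared reads do not account for the rise of those members. Most of them had already been called over all genes, so a high median was fixed in advance. It says nothing on the heavy chain genes, whose values stay uncertain. Quantile normalization left 0.868 ± 0.185, against scaling. A response of the tumours to the antibody may account for the pattern, as a hypothesis found and tested on the same data.

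The cell cycle genes had a lower median with anti-PD-L1 than in control, with 0 of 25 members past over all genes in limma. Camera with an estimated correlation did not call the list (adjusted p = 0.366). The median nearest 0 when 1 library was left out was -0.469 ± 0.131, without anti-PD-L1 library 4, so no single library set it. Dilution of tumour cells by macrophages and endothelial cells would raise the markers of both, whose higher median was -0.626 ± 0.37, although without controls 1 and 2 the endothelial median was -0.08. Both lists had been seen to be lower before this was asked, so the outcome was known and it is no separate test. Dilution by other cells, such as lymphocytes, may contribute and was not tested. Cytotoxic lymphocyte genes had a median of 0.81, with 1 of 7 past over all genes in limma. Fry called that list and camera with an estimated correlation did not (adjusted p = 0.317). No value here separates a change in the tumour cells from a change in cell composition, and both were left open.

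For the sterol genes, members not seen first had a median of -0.77 ± 0.143 for anti-PD-L1 against control, so the fall was not limited to the genes picked as extreme. These members belong to the same pathway and were measured in the same libraries. They therefore cannot exclude a chance shift of the whole pathway that was then picked. The median for the combination against anti-PD-L1 stayed at 0.422 ± 0.148 or higher without each anti-PD-L1 library. For the combination against exercise, which shares no library with anti-PD-L1 against control, the median was -0.02 ± 0.173, and for exercise against control -0.17 ± 0.18, or -0.27 without exercise 1. A change with the antibody that is smaller with exercise may be followed up, as a hypothesis. Its interaction median was 0.76 ± 0.225, and 0.637 ± 0.233 at the lowest without 1 library, which follows in part from values already seen, and camera with an estimated correlation did not call it (unadjusted p of 0.0749).

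The libraries of each comparison were regrouped in 35 ways, the real one included, and for the interaction in 100 drawn ways. For the 30 genes of anti-PD-L1 against control, 1 of 35 splits, the real one, gave as many, and the highest other gave 0. A share of 1 in 35 is the smallest these splits can give. The same was asked of the genes and lists of every comparison without a correction, so chance is not excluded here. For the 16 lists of that comparison, 5 of 35 splits gave as many, with 21 as the highest other, so chance cannot be excluded. For the genes of the other comparisons the real count was 0, which every split reaches (35 of 35, and 100 of 100 for the interaction), so these splits say nothing on chance. The highest other was 928 for exercise against control, 86 for the combination against control, 1 against anti-PD-L1, 533 against exercise and 236 for the interaction. For lists the values were 35 of 35 for exercise against control (real 2, highest other 16), 22 of 35 for the combination against control (real 9, highest other 14), 2 of 35 against anti-PD-L1 (real 16, highest other 16) and 19 of 35 against exercise (real 9, highest other 15), so chance cannot be excluded for these. For the interaction 26 of 100 splits gave as many lists (real 13, highest other 17). Those splits regrouped all 16 libraries and so hold the effects of exercise and antibody as well, and they do not test the interaction alone. The split with 928 genes set controls 1 to 3 and exercise 1 against control 4 and exercise 2 to 4, and the one with 533 set exercise 1 and combination 2 to 4 against combination 1 and exercise 2 to 4. Both point to a structure of the samples that the groups do not follow, in which exercise 1 lies with the other group. Exchanged labels of exercise 1 and control 4 may account for the first, as may exercise 1 alone, since 611 genes passed without exercise 1 and 0 without control 4. This was left open and the labels were kept as given. The results with exercise carry that doubt, and so do all comparisons with control, which use control 4. For anti-PD-L1 against control, far more genes passed without control 4 than with all libraries, as given above.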
